A study of Mus musculus with 4 samples.

How the data were processed

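Flag ChIP-seq was done on lineage-negative bone-marrow cells of 8-week-old mice carrying a triple-Flag-tagged Nynrin transgene, with 2 ChIP libraries and 2 input libraries. Per the labels' protocols, cells were fixed in 1% formaldehyde for 10 min, and libraries were made from 10 ng of DNA with a Vazyme TruePrep kit, a transposase-based kit, with 16 amplification cycles and size selection at 100 to 500 bp. Per the submitters' processing notes, which give no versions or order, the tools were cutadapt, Trimmomatic, FastQC, Bowtie2, MACS2 and ChIPseeker, and the genome build was mm10. Whether the input served as the control for peak calling, and the cutoff used, were not given in the sources used here.

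The authors deposited a peak list for each ChIP library, and the peak names show that peaks were called separately for each. Each deposited peak has a start, an end and a summit. The deposited fold enrichment is a linear ratio of signal over the caller's background at the summit. The deposited −log10 p and −log10 q values are those of the peak caller, and the smallest −log10 q was 1.31 in replicate 1 and 1.30 in replicate 2. The deposited score was 10 times the −log10 q, cut to a whole number, in every peak, and was not used further. Fold enrichment took 2210 distinct values in replicate 1 and 1007 in replicate 2, where the 10 most common values covered 41.5% of peaks, so ranks in replicate 2 held many ties. Peak lists carry no counts, so the depth per library is unknown, and no interval that needs it was given.

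Peaks on chromosomes 1 to 19, X and Y were kept. A replicate's peak had a partner when it overlapped a peak of the other replicate by at least 1 bp. The other list was shuffled 1000 times within the span from the lowest to the highest annotated gene of each chromosome, without masking assembly gaps, and a one-sided permutation p was taken, whose smallest value is 0.001. Alternatives used 100 shuffles. The gene table was that of GRCm38.p6, the assembly behind mm10. It gave the bounds of each gene without strand, transcripts or exons, and no genome sequence was used. The design fixed before the data were examined asked for transcription start sites. In their place, a summit was assigned to a protein-coding gene when it lay within 1000 bp of either end of the gene, and 21887 genes entered. For the same reason exon and untranslated region classes, start sites alone, matching on CpG content and motif searches were not run.

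A gene is termed a called gene when both replicates had such a summit. Each of 34 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test with a conditional odds ratio and exact 95% interval, and p-values were adjusted by Benjamini-Hochberg over the 34 lists. Shares carry exact Clopper-Pearson 95% intervals, which cover the sampling of genes only. Named genes were chosen by a rule fixed before the data were examined. It took Nynrin and every gene of the permeability transition pore list, the 12 genes with the highest score, up to 4 members of each list with the highest score, the 5 strongest shared peaks more than 10000 bp from a gene end, and the 3 strongest peaks of each replicate without a partner. The score was the lower of the gene's percentile ranks by fold enrichment in the 2 lists. The globin genes, the Y-linked genes, and the genes named in the closing section as gained in replicate 2 were named after their values were seen. Where a named gene's peak was also within reach of a neighbour, the neighbour was named once with it. Some genes that the rule selects are not reported here.

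Nothing in the labels says that the 2 replicates came from separate animals, so agreement between them may be technical. The shuffles and Fisher's tests measure spread over positions and genes, not over animals. Alternatives changed the cutoff (−log10 q or fold enrichment of at least 5), the overlap rule (50% of both peaks, or summits within 200 bp), list length, the shuffle, the window (500 or 3000 bp), the replicates used, the treatment of summits near several genes and the background of genes. Where summits near several genes were left out, the genes at those summits stayed in the lists and in the background. A gene end close to another gene's end could then seldom be called.

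The procedures were tested on simulated data. With 60% of replicate 1 sized peaks copied into a random second list, 60.5% were found to overlap, and with none copied, 1.57%. With 40% of summits placed at gene ends, 41.8% were found there, and with none placed, 3.11%. In 50 simulations over the 21887 genes, in which 32% of genes were called, 98% of lists raised to 70% were called higher, 87% of lists lowered to 5% were called lower, and 1.46% of 22 unchanged lists were called. Each gene's call was drawn independently there, while in the data a single peak can call neighbouring genes together. These rates may therefore not hold for the lists tested. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.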

Results

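Chromatin immunoprecipitation with a Flag antibody followed by sequencing (ChIP-seq) was used to map sites bound by Nynrin in lineage-negative bone-marrow cells. These are marrow cells depleted of cells carrying mature-lineage surface markers, and they include the stem and progenitor cells. They came from 8-week-old C57BL/6 mice carrying a transgene for Nynrin with a triple Flag tag. The series holds 4 libraries, 2 of Flag ChIP and 2 of input chromatin. A list of peaks from each Flag ChIP library was analysed, and the input libraries were not analysed here. No library of untagged cells or of a control antibody was used here, so a peak is a site called by the authors' software in a Flag ChIP library and nothing was subtracted further. Positions are in mm10. The peak lists carry no read counts, so the depth behind each peak is unknown.

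How many sites were called, and how far the replicates shared them, was examined first. Replicate 1 held 12702 peaks on chromosomes 1 to 19, X and Y, and replicate 2 held 25787, which was 2.03 times as many. Ranked by the lower of its percentile ranks in the 2 lists, the highest gene was Eif5a, which encodes a translation factor, with a fold enrichment of 13.3 in replicate 1 and 22.5 in replicate 2. It was followed by Vkorc1l1 (10.4 and 17.8), by a peak shared by the neighbours Brca1, a DNA repair gene, and Nbr1, an autophagy receptor gene (9.77 and 15.5), and by Phf12 (9.96 and 13.8). Rbm39, Samd4b with its neighbour Gmfg, the pair Cggbp1 and Zfp654, Larp4b, Atp1b3 and Fxr2 completed the 12 highest-ranking genes, with fold enrichments of 8.80 to 10.8 in replicate 1 and 13.3 to 14.1 in replicate 2. Fold enrichment is the authors' value for each peak. It was used to describe, rank, class and filter peaks within a list, its ranks were correlated between the lists, and its size was not compared between them.

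Of the replicate 1 peaks, 11327 (89.2%) overlapped a replicate 2 peak, against 1.60% when the replicate 2 peaks were placed at random on their chromosomes (p = 0.001, one-sided permutation test, the smallest value 1000 shuffles can give). In the other direction 10783 replicate 2 peaks (41.8%) overlapped a replicate 1 peak, against 0.794% after shuffling (p = 0.001, the same permutation test). The share depended on strength in replicate 2, where 11.3% of peaks in the weakest of 4 equal classes and 88.5% in the strongest had a partner. In replicate 1 these shares were 86.6% and 97.4%. Between lists of equal length, the 12702 peaks with the highest −log10 q in each, the shares were 73.3% of replicate 1 peaks and 68.8% of replicate 2 peaks. When overlap was required to cover 50% of both peaks, the shares of the full lists fell to 47.1% and 23.2%. Across the 11327 shared peaks, which are not independent replicates, the fold enrichments of the 2 lists correlated weakly (Spearman's rho 0.24), and rho was 0.50 for the authors' −log10 q values. Summits of shared peaks lay a median of 120 bp apart.

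**Figure D1:**
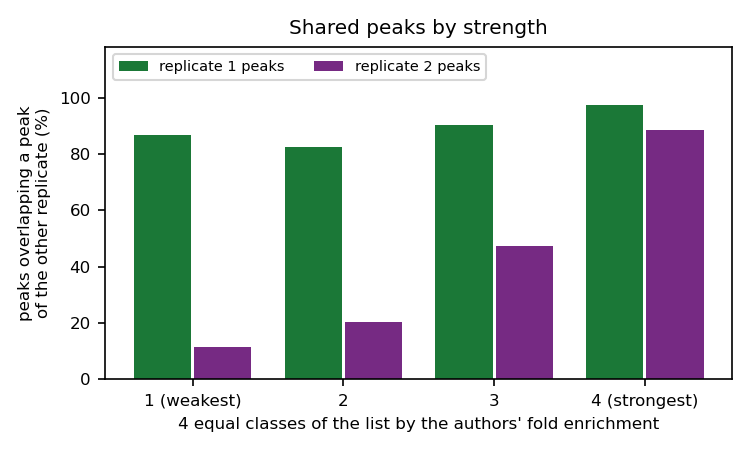
Percent of peaks (vertical axis) that overlap a peak of the other replicate, by 4 equal classes of each list ranked on the authors' fold enrichment (horizontal axis), with bars for replicate 1 (green) and replicate 2 (purple). The share rose from 11.3% to 88.5% across the classes of replicate 2 and lay between 82.6% and 97.4% in replicate 1.

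The strongest peaks without a partner were at other places. In replicate 1 they lay inside Snx31 (fold enrichment 6.41), inside the helicase gene Wrn (6.25) and 18797 bp from Dars (6.53). In replicate 2 they lay inside the cyclin gene Ccnd3 (12.2), inside the nuclear receptor coactivator gene Ncoa2 (11.7) and 28 bp from Atg9a, which encodes an autophagy protein (11.4).

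The series describes promoter binding sites, so the position of summits relative to gene ends was measured. Among shared peaks, 55.3% of summits lay within 1000 bp of an end of a protein-coding gene, against 3.24% of shuffled peaks (p = 0.001, one-sided permutation test, 1000 shuffles). The share was 50.3% in replicate 1 and 36.4% in replicate 2. It was 8.80% for replicate 1 peaks without a partner and 22.3% for replicate 2 peaks without one. The remaining shared summits fell at ends of other genes (5.68%), elsewhere inside protein-coding genes (23.3%) or between genes (15.7%). The annotation used gave gene bounds without strand, so the 5′ and 3′ ends were not told apart. Among 5485 genes longer than 10000 bp whose ends lay more than 10000 bp from any other gene end, 1288 had a summit at a single end in both replicates and 6 had summits at both ends.

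Shared peaks more than 10000 bp from every protein-coding gene end numbered 2513, or 22.2% of all shared peaks, and 19.5% when those at the ends of other genes were left out. The 5 strongest lay inside Usp42 on chromosome 5 (143732068 to 143732725, fold enrichment 8.51 and 12.2), inside Smim14 on chromosome 5 (65492390 to 65493900, 8.78 and 11.96), 11837 bp from Vps52 on chromosome 17 (33978326 to 33979260, 7.87 and 11.4), inside Srrm2 on chromosome 17 (23802646 to 23803548, 7.39 and 12.5) and inside Por on chromosome 5 (135688702 to 135689346, 7.21 and 12.1). Coordinates are those of the replicate 1 peaks.

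In all, 6981 of 21887 protein-coding genes (31.9%) had a summit within 1000 bp of an end in both replicates, and are termed called genes. Replicate 1 gave 7128 such genes and replicate 2 gave 9954. If the replicates were independent, 3242 genes would have been shared. Only 147 genes were called in replicate 1 alone, and 2973 in replicate 2 alone. With −log10 q of at least 5 in both lists, the number of called genes was 4619. It was 6926 when overlapping peaks of the 2 replicates were required at the same gene end.

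The series title concerns the mitochondrial permeability transition pore, a channel of the inner mitochondrial membrane whose opening dissipates the membrane potential, so 26 genes for its candidate components and regulators were examined. Of these, 17 (65.4%, exact 95% interval 44.3 to 82.8%) were called genes, against 31.9% of other genes (odds ratio 4.04, exact 95% interval 1.70 to 10.3, adjusted p = 9.07e-04, two-sided Fisher's exact test over 34 lists). They included Ppif, which encodes cyclophilin D, the best-established regulator of the pore. The Ppif gene spans 25693574 to 25700468 on chromosome 14, and its peaks ran from 25693797 to 25694559 in replicate 1 and from 25693773 to 25694680 in replicate 2. Both summits were inside the gene, 493 and 664 bp from its lower-coordinate end, with fold enrichments of 6.13 and 6.38. With a 500 bp window Ppif was not a called gene.

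**Figure D2:**
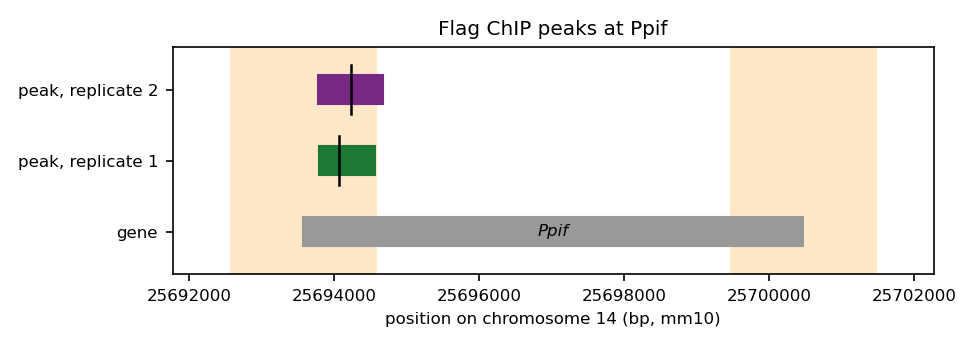
Map of Ppif on chromosome 14 (horizontal axis, position in bp, mm10) with the gene in grey, the peaks of replicate 1 (green) and replicate 2 (purple), their summits as black lines, and the 1000 bp windows around both gene ends shaded. Both summits lie inside the gene, 493 and 664 bp from its lower-coordinate end.

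The strongest members of this list were Spg7, which encodes a mitochondrial protease subunit (fold enrichment 6.76 in replicate 1 and 11.7 in replicate 2), the outer-membrane channel gene Vdac3 (6.37 and 10.1), the ATP synthase subunit gene Atp5b (6.54 and 9.30) and the kinase gene Gsk3b (5.43 and 11.2). Vdac1, Vdac2, the phosphate carrier gene Slc25a3, Atp5g1, Atp5g2, Atp5o, Trap1, Hk2, Bcl2 and Bax were also called genes, as were Atp5a1 and Atpif1, which shared their peaks with the neighbours Haus1 and Dnajc8. Bax ranked low in replicate 1, with a fold enrichment of 2.49. Atp5g3 had a summit in replicate 1 alone, and Tspo, Bak1 and the adenine nucleotide translocator gene Slc25a5 had one in replicate 2 alone. The other translocator genes Slc25a4 and Slc25a31, and Hk1, Ckmt1 and Bcl2l1, had none in either. Of the 26 genes, 13 also belonged to another of the lists.

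Nynrin itself, at 55854115 to 55874736 on chromosome 14, was not a called gene. Replicate 2 had a weak peak there (55873929 to 55874350, fold enrichment 3.44, −log10 q 3.56), inside the gene and 466 bp from its higher-coordinate end, and replicate 1 had none within 1000 bp of the gene.

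Which other groups of genes were called was tested with 34 lists fixed before the data were examined. Of these, 19 held a higher share of called genes than other genes and 11 a lower share, and 4 did not pass the test (Benjamini-Hochberg adjusted p under 0.05, two-sided Fisher's exact test). Genes are not independent replicates, and the intervals cover the sampling of genes only. Of the 28 lists with an odds ratio above 0, 27 had one that moved by over 1.5 times under at least 1 alternative, and the pore list did not. Moves toward stronger and toward weaker association were both counted. The pore list's odds ratio of 4.04 itself ranged from 3.64 to 5.74. No list was tested with the 500 bp window.

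In the mitochondrial groups other than the pore list (65.4%), 71.0 to 79.3% of members were called genes. Of 36 nuclear genes for respiratory complex I, 27 were called (adjusted p = 4.60e-07, Fisher's exact test), led by Ndufs7 and by Ndufs1, whose peak was shared with Eef1b2. Of 31 genes for complexes II, III and IV, 24 were called (adjusted p = 6.99e-07, Fisher's exact test), among them Uqcrh (fold enrichment 7.58 and 11.5), Uqcrq, Sdha and Cox6a1. The first 3 shared their peaks with Lrrc41, Gdf9 and Ccdc127. Of 75 mitochondrial ribosomal protein genes, 57 were called (odds ratio 6.81, adjusted p = 5.79e-14, Fisher's exact test). The odds ratio was 3.12 with −log10 q of at least 5, 16.9 in replicate 2 alone and 1.81 without summits near the ends of more than 1 gene (adjusted p = 0.0289, range over alternatives 1.01e-17 to 0.0289, Fisher's exact test). Mrps18b, which shared its peak with Ppp1r10, ranked highest (8.27 and 14.9), ahead of Mrpl10 (with Lrrc46) and Mrps7 (with Gga3). Of 29 pyruvate dehydrogenase and tricarboxylic acid cycle genes, 23 were called, including Dlst with its neighbour Prox2, Idh3a, and Pdhx with Apip (adjusted p = 6.25e-07, Fisher's exact test). Of 31 genes for mitochondrial fusion, fission, biogenesis and mitophagy, 22 were called, including Immt, Tomm40, Yme1l1 and Phb2 (adjusted p = 4.15e-05, Fisher's exact test). The last 3 shared their peaks with Nectin2, Mastl and Emg1. Of 12 mitochondrial calcium genes, 9 were called, including Smdt1 with its neighbour Pheta2, Ghitm, Mcur1 and Afg3l2 (adjusted p = 0.00357, Fisher's exact test). Of 17 ATP synthase genes, 13 were called, including Atp5md with its neighbour Pdcd11, and Atp5l (adjusted p = 3.90e-04, Fisher's exact test). This last call was lost when summits near the ends of more than 1 gene were left out, a setting chosen after the data were seen (odds ratio 1.97 against 6.95, adjusted p = 0.239, range over its alternatives 6.48e-05 to 0.239, Fisher's exact test). Gene ends close to another gene's end can seldom be called under this setting, but their genes stayed in the lists. The loss, and the lower odds ratio of the mitochondrial ribosomal genes, therefore cannot show that these associations are fragile.

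Genes of the basic machinery of every cell were called most often. Of 78 cytosolic ribosomal protein genes, 70 were called (89.7%, odds ratio 18.9, adjusted p = 2.87e-25, Fisher's exact test), among them Rps15, Rpl9 with its neighbour Lias, Rps29 and Rps23. The odds ratio was 7.13 with −log10 q of at least 5, 8.22 without summits near several genes and 43.3 with a 3000 bp window (adjusted p from 7.48e-28 to 6.52e-16 over all alternatives, Fisher's exact test). Of 41 spliceosome genes, 37 were called, including Sf1, Hnrnpa1 (with Cbx5), Ddx5 (with Cep95) and Srsf5, and of 34 proteasome genes, 30 were called, including Psmc6, Psma3 and Psmd11. Of 28 heat shock and unfolded protein response genes, 25 were called, with Dnaja1 (7.77 and 11.2), Ddit3, Hspa5 and Atf4 ranking highest. Dnaja1 shared its peak with Aptx and Ddit3 with Mbd6. The adjusted p-values of these 3 lists were 7.98e-14, 8.99e-11 and 2.03e-09 by Fisher's exact test.

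Of 40 cell cycle genes, 30 were called, including Cdc6 (6.76 and 12.9), the cyclin-dependent kinase inhibitor genes Cdkn2c and Cdkn1b, and Ccna2 with its neighbour Bbs7. Of 63 replication-dependent histone genes, 43 were called, led by the adjacent pairs H2ac11 with H2bc11 and H2bc18 with H3c13. Of 28 genes of the p53 pathway and DNA damage response, 17 were called, including Brca1, H2ax (with Dpagt1), Lig4 (with Abhd13) and Fanca. The adjusted p-values of the 3 lists were 1.01e-07, 1.83e-08 and 0.00254 by Fisher's exact test. Leaving out summits near several genes ended the histone call (odds ratio 1.45 against 4.61, adjusted p = 0.232, range over alternatives 1.47e-15 to 0.232, Fisher's exact test) and the p53 call (odds ratio 2.01 against 3.31, adjusted p = 0.117, range 5.40e-07 to 0.117, Fisher's exact test). Adjacent genes such as the histone pairs can seldom be called under this setting, so these losses cannot show that the calls are fragile.

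Of 28 antioxidant genes, 19 were called, including Prdx5 with its neighbours Esrra and Trmt112, Gsr, Keap1 and Prdx6, and of 29 interferon response genes, 17 were called, including Ifnar1, Irf9 (with Rnf31) and Stat2 (with Apof). Of 25 immediate early genes, 16 were called, including Klf2, Dusp1, Egr1 and Btg2. The strongest Klf2 peaks of the 2 replicates lay at opposite ends of the gene. The adjusted p-values of the 3 lists were 2.44e-04, 0.00525 and 0.00159 by Fisher's exact test. Of 31 apoptosis genes, 16 were called (adjusted p = 0.0359, Fisher's exact test), including Birc5, Bcl2l11 (with Acoxl), Casp9 and Apaf1 (with Ikbip). That call was lost at −log10 q of at least 5 (adjusted p = 0.0865, range over alternatives 6.17e-04 to 0.0865, Fisher's exact test) and without olfactory and vomeronasal receptor genes in the background (0.0617), where the odds ratio was 2.06 in both against 2.28.

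The 4 lists that did not pass the test held stem and progenitor, neutrophil and monocyte, glycolysis and erythroid genes. Of 50 stem and progenitor cell genes 12 were called (24.0%, exact 95% interval 13.1 to 38.2%, adjusted p = 0.296, Fisher's exact test), which did not differ detectably from other genes. They included Tek (8.78 and 17.4), the chemokine receptor gene Cxcr4 (6.25 and 11.2), Runx1 (5.45 and 10.9) and Egr1. Their odds ratio was 0.67, against 1.15 with a 3000 bp window and 1.96 in replicate 2 alone (adjusted p = 0.661 and 0.0238, range over alternatives 0.0238 to 0.661, Fisher's exact test). Of 33 neutrophil and monocyte genes, 11 were called (adjusted p = 0.853, Fisher's exact test), among them S100a8, S100a9, Mmp8 and Itgam. Their odds ratio was 1.07, against 0.831 at −log10 q of at least 5, 0.963 without receptor genes in the background and 3.20 in replicate 2 alone (adjusted p = 0.00280 for the last, range over alternatives 0.00280 to 1.0, Fisher's exact test). Of 25 glycolysis genes, 11 were called (adjusted p = 0.214, Fisher's exact test), including Arnt, Pgam1, Pfkfb3 and Slc16a3, and in replicate 2 alone their odds ratio was 6.30 (adjusted p = 2.22e-04, range over alternatives 2.22e-04 to 0.504, Fisher's exact test). Of 27 erythroid genes, 4 were called, which were Nfe2, Blvrb with its neighbour Sptbn4, Urod with Hectd3, and Tfrc (adjusted p = 0.0693, Fisher's exact test). They passed the threshold as a lower share without the receptor genes (adjusted p = 0.0462, range over alternatives 0.0462 to 0.655, Fisher's exact test). The globin genes Hba-a1, Hbb-bs and Hbb-bt had no summit in either replicate.

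The remaining lists fell below other genes. Of 20 megakaryocyte genes, 1 was called (Plek), of 24 B lymphoid genes 1 (Tcf3), and of 30 T and NK cell genes 3 (Cd3d, Tbx21, and Cd27 with its neighbour Tapbpl), with adjusted p of 0.00868, 0.00241 and 0.0112 by Fisher's exact test. The strongest peaks of Tbx21, and those of Cd27, did not overlap between the replicates. Liver and muscle lists each had 1 called gene, Hp of 24, and of 27 Actn3 with its neighbour Zdhhc24 (adjusted p = 0.00241 and 0.00109, Fisher's exact test). None of 19 mast cell, basophil and eosinophil genes, 25 stromal and endothelial genes, 28 neuronal genes, 25 epithelial genes or 1110 olfactory receptor genes was called (adjusted p from 4.06e-190 to 0.00145, Fisher's exact test). None of 58 developmental transcription factor genes was called either (adjusted p = 1.42e-09, Fisher's exact test), where the exact 95% interval allowed up to 6.16%. The megakaryocyte and B lymphoid calls were lost at −log10 q of at least 5 and with a 3000 bp window, and the megakaryocyte call in replicate 2 alone as well. Their odds ratios of 0.112 and 0.0927 went to 0.197 and 0.162 at the stricter q and to 0.303 and 0.452 with the wider window, and the megakaryocyte value was 0.399 in replicate 2 alone (adjusted p = 0.111 and 0.0526 at the stricter q, ranges over alternatives 0.00502 to 0.116 and 0.00111 to 0.151, Fisher's exact test). Without summits near several genes those of the T and NK cell and liver lists were lost too, with odds ratios of 0.258 and 0.157 against 0.237 and 0.0927 (adjusted p = 0.0592 and 0.0591, ranges 0.00254 to 0.0592 and 2.12e-04 to 0.0591, Fisher's exact test).

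**Figure D3:**
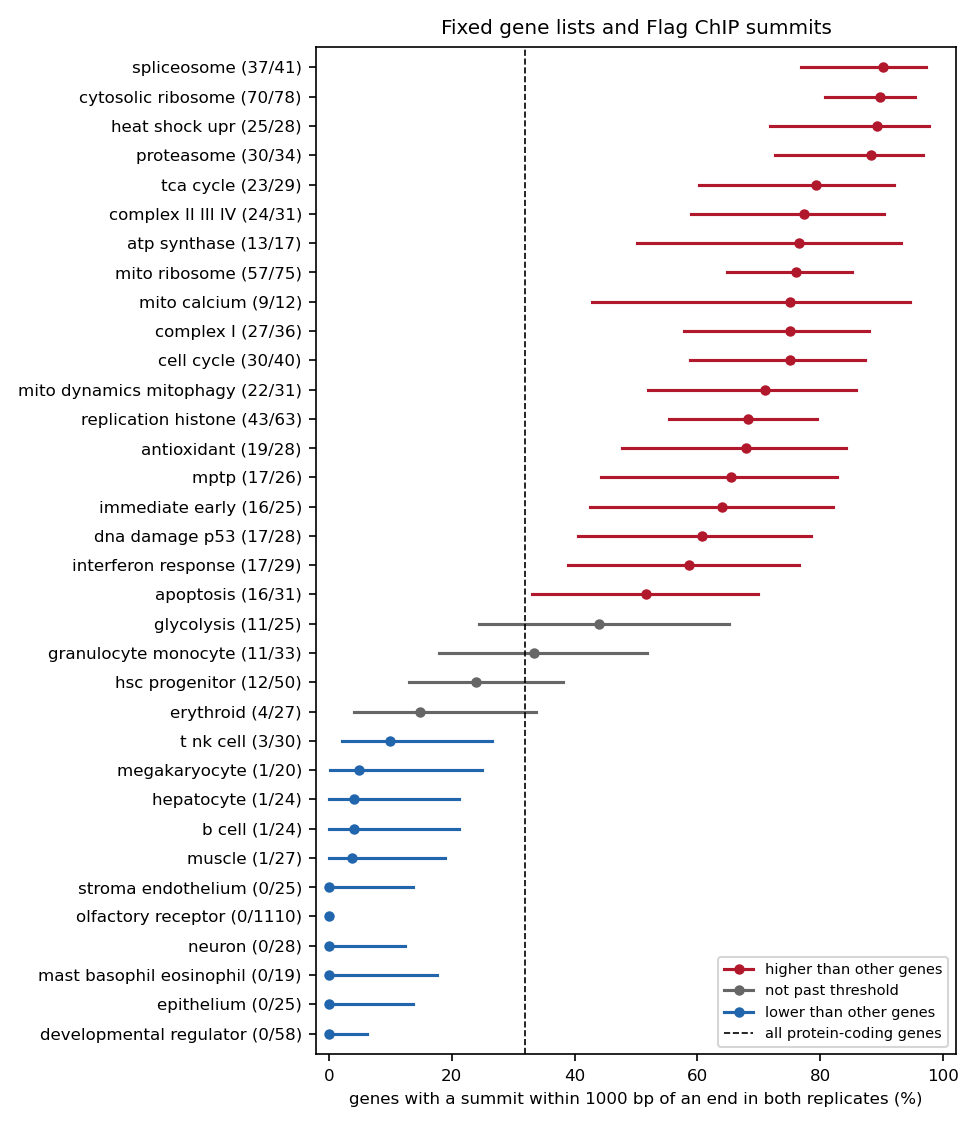
Percent of each list's genes called in both replicates (horizontal axis) for the 34 lists (vertical axis, with called and total genes), as points with exact 95% binomial intervals as lines, coloured by the result of Fisher's exact test, and the 31.9% of all protein-coding genes as a dashed line. The basic machinery and mitochondrial lists lie to the right of the dashed line, and the lists of other tissues to its left.

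The share of called genes differed between chromosomes. On chromosome X, 48 of 966 genes were called (4.97%, exact 95% interval 3.69 to 6.53%), while the autosomes ranged from 26.6% on chromosome 14 to 39.7% on chromosome 19. The share on X was 5.28% in replicate 1 and 18.0% in replicate 2. On chromosome Y, 2 of 256 genes were called, Eif2s3y and Uty.

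**Figure D4:**
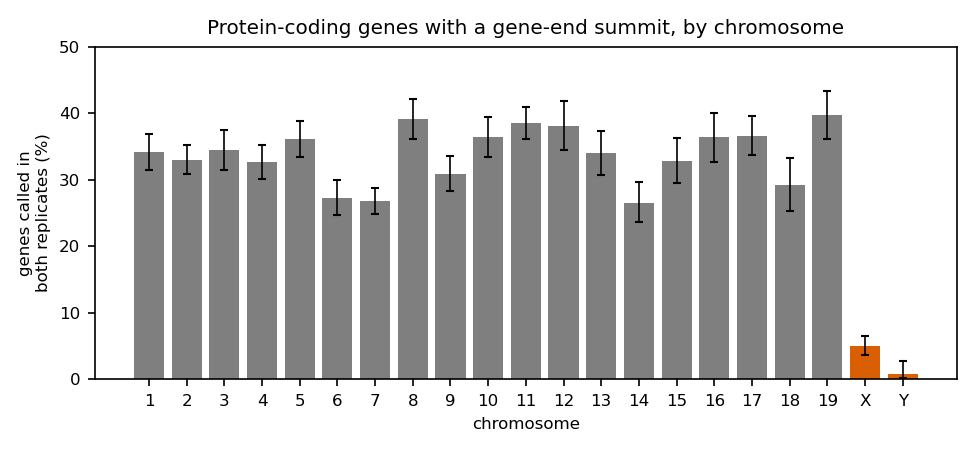
Percent of protein-coding genes called in both replicates (vertical axis) on each chromosome (horizontal axis), with autosomes in grey, X and Y in orange, and exact 95% binomial intervals as error bars. Chromosome X, at 4.97%, lies below the lowest autosome, chromosome 14 at 26.6%.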

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

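Peaks also appeared outside the chromosomes used in the comparisons, 14 in replicate 1 and 20 in replicate 2. They were singled out because they are a signal in data that no comparison used. In each replicate 3 of them lay on the mitochondrial genome, and the others on sequences outside the assembled chromosomes. The highest fold enrichment, on such a sequence, was 15.3 in replicate 1 and 16.5 in replicate 2. The mitochondrial peaks had low fold enrichments, 1.18 to 2.23 in replicate 1 and 1.66 to 1.76 in replicate 2. Their −log10 q reached 153 and 96.8, the highest of these peaks. No explanation for these peaks was tested.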

How the results depend on the processing

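Settings that left out summits near several genes, used every gene biotype, removed receptor genes from the background, split shared peaks by gene ends, or counted pore genes in a single replicate were chosen after the data were seen. With −log10 q of at least 5, peaks numbered 6386 in replicate 1 and 15024 in replicate 2, and called genes 4619. With fold enrichment of at least 5, peaks numbered 2923 and 11332. These counts fell because fewer peaks entered. The agreement of enrichment (rho 0.24) moved to 0.50 with −log10 q, 0.27 with summits within 200 bp and 0.31 at gene-end peaks, and was 0.14 at the other shared peaks. The cause was not tested. The number of lists called lower fell from 11 to 7 without summits near several genes, where fewer genes were called (4739). Called genes ranged from 7128 to 9954 when a single replicate was used. The odds ratio of the stem and progenitor list was 0.67 in both replicates, ranged from 0.727 to 1.96 with a single replicate, and was 1.15 with a 3000 bp window. That of the neutrophil and monocyte list went from 1.07 to 0.831 at −log10 q of at least 5 and 0.963 without receptor genes, neither past the threshold. With replicate 2 alone the stem and progenitor (1.96, the opposite direction), neutrophil and monocyte (3.20) and glycolysis (6.30) lists passed the threshold as higher. Without receptor genes the erythroid list passed it as lower (0.335). The causes were not tested. Shared peaks stayed above their shuffled share in all 5 alternatives in each direction, and gene-end shares in all 4. The pore list held 13 to 20 called genes over its alternatives and stayed past the threshold in all that were run (adjusted p from 8.49e-05 to 0.00211, Fisher's exact test). Neither the 500 bp window nor overlapping peaks at the same gene end was run for the pore list or any other list. Individual list calls were lost in 3 lists with −log10 q of at least 5, in 2 with a 3000 bp window, in 1 with replicate 2 alone, in 1 without receptor genes and in 7 without summits near several genes. In that last setting a gene end close to another gene's end can seldom be called, so its losses cannot show fragile calls. No paired analysis was possible because the input libraries were not analysed here. Start sites alone, matching on CpG content and motif searches were not run. Depth is unknown from peak lists, so how far it limits replicate 1 could not be measured.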

Other observations

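The tests of CpG-rich sequence, of replicate 2 peaks at matched fold enrichment, of genes gained in replicate 2, of constitutive X genes in replicate 2 alone of the rise of less often called lists and of halved fold enrichment, and the values for transfer RNA genes, were chosen after the results were seen. Transfer RNA genes, which RNA polymerase III transcribes, had a summit within 1000 bp of an end in both replicates at 152 of 408 (37.3%, exact 95% interval 32.5 to 42.1%). Among those more than 2000 bp from any protein-coding gene end the share was 104 of 341 (30.5%). At the same distance it was 3.09% of 9503 long noncoding RNA genes, 3.32% of 935 small nuclear RNA genes, 0.512% of 1171 small nucleolar RNA genes and 0.288% of 9364 pseudogenes. A single peak can call neighbouring genes together, and distinct peaks were not counted. The transfer RNA genes may therefore stand for fewer sites, and the interval treats genes as independent.

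Genes called in replicate 2 and not in replicate 1 included some of the blood lists and more of other lists. Among the 14759 genes without a gene-end summit in replicate 1, 20.1% had one in replicate 2. The share was 19 of 37 in the stem and progenitor list (51.4%, odds ratio 4.20, adjusted p = 1.31e-04, two-sided Fisher's exact test over 34 lists), including Kit, Flt3, Gata2, Myb, Meis1, Hlf and Myc. It was 13 of 22 in the neutrophil and monocyte list (odds ratio 5.75, adjusted p = 2.94e-04, Fisher's exact test), including Elane, Prtn3, Ctsg, Irf8 and Cebpa, 10 of 14 in glycolysis, 8 of 9 for complex I and 9 of 11 for the p53 pathway. The erythroid (3 of 23), megakaryocyte (4 of 19), B lymphoid (2 of 23), T and NK cell (3 of 26) and mast cell, basophil and eosinophil (2 of 19) lists did not pass the test (adjusted p from 0.370 to 1.0, Fisher's exact test). In all 17 lists were higher and 2 lower, the olfactory receptors and the developmental transcription factors, where 0 of 58 genes were gained.

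Mitochondrial gene lists were called more often than other genes. General signal at constitutively active promoters is a candidate explanation: 182 of 246 mitochondrial genes were called (74.0%) against 137 of 153 ribosome, spliceosome and proteasome genes (89.5%), an odds ratio of 0.333 (exact 95% interval 0.172 to 0.614). In replicate 2 alone the shares lay closer, at 76.9 to 97.2% in the mitochondrial lists and 93.6 to 97.6% in the others. CpG-rich sequence alone is argued against, since the developmental transcription factor list, chosen for CpG-rich promoters, had an upper bound of 6.16% where the mitochondrial lists had a lower bound of 68.0%. CpG content itself was not measured. Whether the Flag signal marks Nynrin binding at these promoters stays open, because no untagged library was analysed here, and no biological explanation was tested.

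Chromosome X had a lower share of called genes than any autosome, and fewer peaks. Peaks on X numbered 0.410 per Mb in replicate 1 and 1.42 in replicate 2, against 3.44 and 6.75 on chromosome 14, the lowest autosome. Fewer gene ends alone would not give this lack of peaks. The share of X genes with a summit was 18.0% even in replicate 2, below the lowest autosome at 37.0%. Of 6 constitutive genes on X, 2 were called in both replicates (33.3%, exact 95% interval 4.33 to 77.7%). This lay below the 83.7% on autosomes (p = 0.00928, two-sided Fisher's exact test). By the criterion set before this test, an interval wholly below the autosomal share argues against tissue-restricted gene families. That criterion was met with both replicates. In replicate 2 alone 4 were called (66.7%, interval 22.3 to 95.7%), where the interval reached the autosomal 95.4%. With this disagreement, and only 6 genes that were all chosen as constitutive, the test cannot decide. Tissue-restricted families stay open for X. Lower copy number of X stays open too. The ratio of X to autosomes in the share called rose 2.47 times from the shorter list to the longer (95% interval 1.79 to 3.45). Lower copy number predicts such a rise. That of the 11 lists called less often than other genes, pooled without X genes, rose 2.90 times (interval 1.31 to 7.29, from 8 called genes to 32). These lists were chosen for few called genes in the same data, which favours a rise, so they cannot show whether the rise is particular to X. Both intervals count the calls of the 2 replicates as independent, though the same genes were scored in both, so they do not measure the spread of the rise. If fold enrichment were halved, 21.3% of called autosomal genes in replicate 1 and 45.4% in replicate 2 would stay at or above a cutoff. The cutoffs were 2.76 and 3.62, the values below which the weakest 5% lay. The shares on X were 15.4% and 38.1% of the autosomal ones. These cutoffs were assumed, and weaker peaks were called in both lists. That lower copy number would halve fold enrichment was assumed too, since the background used by the caller is not known. This comparison therefore cannot decide on copy number. The labels do not give the animals' sex. Summits at the Y-linked genes Eif2s3y and Uty in both replicates, and at Ddx3y in replicate 1, point to Y-bearing cells in both libraries. That goes with lower copy number of X, but the share of such cells was not measured. Lower activity of X was not tested.

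Replicate 2 had more peaks than replicate 1. A longer list that reaches weaker sites of the same set may account for part of this, since replicate 2 peaks without a partner had a median fold enrichment of 3.99 against 6.64 with one, and 89.2% of replicate 1 peaks had a partner. Whether the added peaks are sites of the same kind cannot be told apart from noise in fold enrichment. Within 10 classes of fold enrichment, peaks with a partner still lay at gene ends more often (Mantel-Haenszel odds ratio 1.38, 95% interval 1.29 to 1.48), which an imprecise measure of strength would also give. A difference in the cells of the 2 libraries stays open.

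Inside Nynrin more than 1000 bp from its ends there were 0 peaks, as in 73.4% of 2762 genes of similar length, so this count cannot tell whether extra copies of Nynrin sequence from the transgene added peaks. In replicate 2, 66.3% of fold enrichments were whole multiples of 0.266 (within 0.01 of a step), and in replicate 1, 15.7% were whole multiples of 0.284. Each step was taken from the spacing of the 10 most common values of the same list. Those values alone covered 41.5% of replicate 2 peaks and 12.8% of replicate 1 peaks. The shares were thus partly set by that choice, and no chance rate was obtained for them.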
